A study of Caenorhabditis elegans with 4 samples.

How the data were processed

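Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on young adult hermaphrodite Caenorhabditis elegans grown at 20 °C, per the labels. The worms carried a transgene in which GEI-11 is fused to green fluorescent protein (GFP) and a FLAG tag, and the fusion was collected with an anti-GFP antibody. The 4 samples were 2 ChIP samples and 2 input samples, the latter being whole chromatin saved before the immunoprecipitation. The labels number both kinds 1 and 2 and do not say whether the numbers stand for separate worm cultures, so the spread between replicates may be technical.

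The material analysed was 3 peak lists, 1 for each ChIP replicate and 1 combined list. Per the file headers, positions are on WormBase WS220 and the peaks carry PeakSeq as their source, a caller that scores ChIP reads against an input control. The score that the authors deposited for each peak is a q-value, below 0.01 throughout; it is not a height or a fold enrichment, and it falls with sequencing depth as well as with enrichment. The PeakSeq version, the aligner, the read filters, the q threshold and whether reads were pooled for the combined list are not given in the sources used here. Read counts were not analysed here, so the depth behind each list is unknown, and confidence intervals (exact Clopper-Pearson, 95%) cover the counting of peaks only and treat peaks as independent. No peak list of the input samples was used, so no ChIP sample was compared with input here.

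Peak strength is given as −log10 q. Peaks of 2 lists were called shared when they overlapped by at least 1 bp. Overlaps, and the share of chromosome IV peaks in fixed regions, were tested with one-sided circular-shift permutation tests: each chromosome's peaks were moved together by a random offset 1000 times, which keeps widths and spacing, so the smallest p is 0.000999. Chromosome counts were compared with each chromosome's share of the total extent by two-sided exact binomial tests. The extent of a chromosome was taken as the distance from position 1 to the end of the last peak in any list, 100.1 Mb over 6 chromosomes, because no WS220 chromosome lengths were used here. Medians and correlations across peaks were tested with 100000 permutations, two-sided, with a smallest p of 1e-05. Adjusted p-values are Benjamini-Hochberg within each family of tests. The piRNA domains were set, before the data were examined, as 0.5 Mb bins 10 to 14 (the left domain, 4.5 to 7.0 Mb) and 28 to 34 (the right domain, 13.5 to 17.0 Mb) of chromosome IV. The peaks to be named were, by a rule also set before, the 15 strongest of the combined list, with the strongest members of each region as further examples.

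Tests at gene starts, by RNA class and gene list, and a search for the upstream motif of piRNA genes had been planned. They were not run: the gene table used here is of the assembly WBcel235, whose coordinates were not mixed with WS220, and no genome sequence was used, so peaks are named by position and not by gene. Peak strength was compared for the piRNA domains in place of RNA classes.

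The overlap, domain, chromosome, edge, median and correlation functions were tested on simulated data, with 50 draws of each case and 200 shifts per overlap or domain test. Lists of 2811 peaks with the domains made 4 times as dense gave a mean ratio of 3.90 and a p below 0.05 in 50 of 50 draws, against 3 of 50 with none planted. Lists of 301 peaks with 60% of overlaps planted gave a mean of 60.4% and a p below 0.05 in 50 of 50 draws, against 1 of 50 with none planted. Simulated peaks were placed independently of each other and lack the clustering of the real lists. These counts check the functions and do not give the power or error rate of the shift tests on the real lists. Alternatives covered the overlap rule, the stronger 50% of each list, random placement of single peaks, merging of peaks within 1 kb, and each replicate list in place of the combined one. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.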

Results

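GEI-11, also named SNPC-4, is the C. elegans counterpart of the largest subunit of the small nuclear RNA activating complex, which drives transcription of small nuclear RNA genes. The study mapped where the tagged protein sits on the genome of young adults. The list of ChIP replicate 1 held 301 peaks, that of replicate 2 held 2140 and the combined list 2811. Median peak widths were 336 bp, 289 bp and 288 bp, and the combined peaks covered 907 kb in all. The median −log10 q was 4.74 in replicate 1, 3.15 in replicate 2 and 3.26 in the combined list. The comparisons that follow ask whether the replicates marked the same regions, how the peaks were spread over the chromosomes, and how they lay around the piRNA domains of chromosome IV.

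The regions of replicate 1 were nearly all found again in replicate 2, though the strongest replicate 1 peak was not. Of the 301 replicate 1 peaks, 293 overlapped a replicate 2 peak, a share of 97.3% (95% CI 94.8 to 98.8). Shifted lists gave 2.07% on average and 5.98% at most (circular-shift permutation p = 0.000999, the smallest possible; adjusted p = 0.000999). In the other direction 291 of 2140 replicate 2 peaks, or 13.6% (12.2 to 15.1), overlapped a replicate 1 peak, against 0.292% in shifted lists (circular-shift permutation p = 0.000999, adjusted p = 0.000999). Replicate 2 held 7.11 times as many peaks as replicate 1. The replicate 2 peaks shared with replicate 1 had a median rank of 148 among the 2140, and a median −log10 q of 16.2 against 2.95 for the unshared ones. Cut to its 301 strongest peaks, replicate 2 still overlapped 245 replicate 1 peaks, or 81.4% (76.5 to 85.6). Across the 293 matched peaks, −log10 q in the replicates had a Pearson r of 0.938 and a Spearman rho of 0.879 (permutation p = 1e-05 for each, the smallest possible). Peaks are not independent replicates, so these values describe the lists. In 291 of the 293 matched peaks the value was higher in replicate 2, with medians of 16.2 and 4.93.

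The strongest combined peaks lay on every chromosome, and the 15 strongest were all present in both replicates. The combined ranking comes from the same replicates, so this is no independent sign of their agreement. Chromosome II held 6 of them, chromosome IV 3, chromosomes I and III 2 each, and V and X 1 each. The strongest peak spanned 5543250 to 5544488 on chromosome II, with a −log10 q of 212 in the combined list, 51.8 in replicate 1 and 182 in replicate 2. The second spanned 13834223 to 13835204 on chromosome II, with a combined value of 206. The third, 14476526 to 14477768, was on the X chromosome, with a combined value of 177, and was one of only 2 X peaks among the first 100. The fourth was on chromosome III at 10989190 to 10989972, with a combined value of 161. Chromosome II also held peaks at 14804031 to 14804892 and 15025461 to 15026198, each with a combined value of 149. On chromosome I the strongest combined peak spanned 4171746 to 4172664, with a value of 142. On chromosome V it spanned 8500134 to 8500768, with a value of 141. Of these 15 peaks, 13 were also among the first 15 of replicate 2.

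The combined list held nearly all peaks of both replicates, and its weak peaks were the least often found in the single lists. Of the 2811 combined peaks, 2040 (72.6%, 95% CI 70.9 to 74.2) overlapped a replicate 2 peak and 295 (10.5%, 9.39 to 11.7) a replicate 1 peak. These shares are bounded by the lengths of the replicate lists. Both were far above those of shifted lists, 1.69% and 0.284% (circular-shift permutation p = 0.000999 for each, adjusted p = 0.000999). The combined list comes from the same 2 ChIP replicates, so a high overlap was built in and the test is no evidence of agreement. Peaks found in both replicates numbered 288, with a median −log10 q of 21.2. A further 1752 were found in replicate 2 alone and 7 in replicate 1 alone. The remaining 764 peaks, 27.2% of the combined list, were in neither replicate list and had a median −log10 q of 2.35. All of the 100 strongest combined peaks were in both lists, by a ranking that comes from the same replicates. In ranks 101 to 300, 77.0% were in replicate 1 and 200 of 200 in replicate 2. In ranks 1001 to 2811 these shares were 0.221% and 58.0%. In reverse, 300 of 301 replicate 1 peaks and 2048 of 2140 replicate 2 peaks (95.7%) were in the combined list. The exception in replicate 1 was the strongest peak of replicate 1, at 15064021 to 15067623 on chromosome I, 3603 bp wide with a −log10 q of 276, which no replicate 2 peak overlapped. It lies at the right end of the chromosome, where the ribosomal DNA repeats are found. A combined peak that replicate 2 also held lay nearby, at 15060784 to 15060826.

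**Figure D1:**
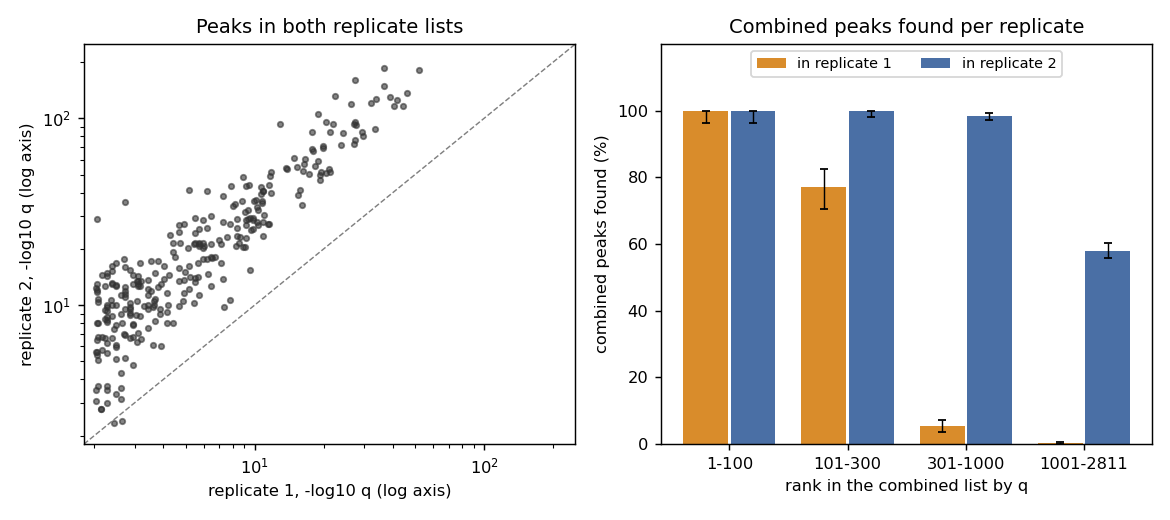
Left, −log10 q of the 293 matched peaks in replicate 1 (x) and replicate 2 (y), both on log axes, with the line of equality dashed; 291 points lie above it. Right, percentage of combined peaks found in each replicate list by rank in the combined list, with exact 95% intervals as bars; the share in replicate 1 falls from 100% in the first 100 peaks to 0.221% in the last tier.

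Chromosome IV carried more peaks than its length would give, and chromosome I fewer, in the combined list and in each replicate. The combined list had 1090 peaks on chromosome IV, 38.8% (95% CI 37.0 to 40.6) against 17.4% of the extent, or 2.22 times the expected count (exact binomial adjusted p = 4.2e-156). The ratio was 2.86 in replicate 1 and 2.35 in replicate 2. Chromosome I had 141 peaks where 423 were expected by length, a ratio of 0.333 (0.281 to 0.391; exact binomial adjusted p = 1.7e-63). That ratio was 0.353 in replicate 1 and 0.310 in replicate 2. Chromosome V (0.732), the X (0.844) and chromosome II (0.891) were also below expectation (exact binomial adjusted p = 8.1e-14, 0.00015 and 0.016), and chromosome III did not pass the test at 0.908 (exact binomial adjusted p = 0.052). The X ratio was 0.358 in replicate 1 and 0.788 in replicate 2. These shares depend on the piRNA domains. With the domain bins left out, a setting chosen after seeing the data, the ratio was 0.949 for chromosome IV and 0.993 for V, neither of which passed the test. The chromosome IV count still included 38 peaks of the dense bin just right of the right domain, from 17.0 to 17.46 Mb. The ratio of 0.949 is therefore too high for chromosome IV away from its dense stretches. It then rose to 1.21 for II, 1.23 for III and 1.15 for the X, all passing, while chromosome I stayed low at 0.452 (exact binomial adjusted p = 3.4e-30). Neighbouring peaks are not independent, so these p-values cover counting error only.

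The X chromosome held few of the 100 strongest peaks. Of the first 100 combined peaks 56 lay outside chromosome IV, and 2 of those, 3.57% (95% CI 0.435 to 12.3), were on the X, which makes up 21.3% of that extent. The share was 17.0% (9.87 to 26.6) in ranks 101 to 300, an interval that includes the share of the extent, 23.6% in ranks 301 to 1000 and 26.1% (23.6 to 28.7) in ranks 1001 to 2811. These rank tiers were chosen after seeing the data. Between the stronger and weaker 50% of the list the X share outside chromosome IV was 21.9% and 26.3%, a difference that did not hold after adjustment over the 5 chromosomes (Fisher's exact p = 0.032, adjusted p = 0.086). In replicate 1, 19 of 301 peaks (6.31%) were on the X, and in replicate 2, 297 of 2140 (13.9%; Fisher's exact p = 0.00011, adjusted p = 0.00075). At matched length, with the 301 strongest of replicate 2, both lists had 19 X peaks. The lists are not independent, as 293 of the 301 replicate 1 peaks overlapped replicate 2 peaks and 245 did so at matched length. The comparison of the replicates by Fisher's exact test therefore describes the lists only.

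**Figure D2:**
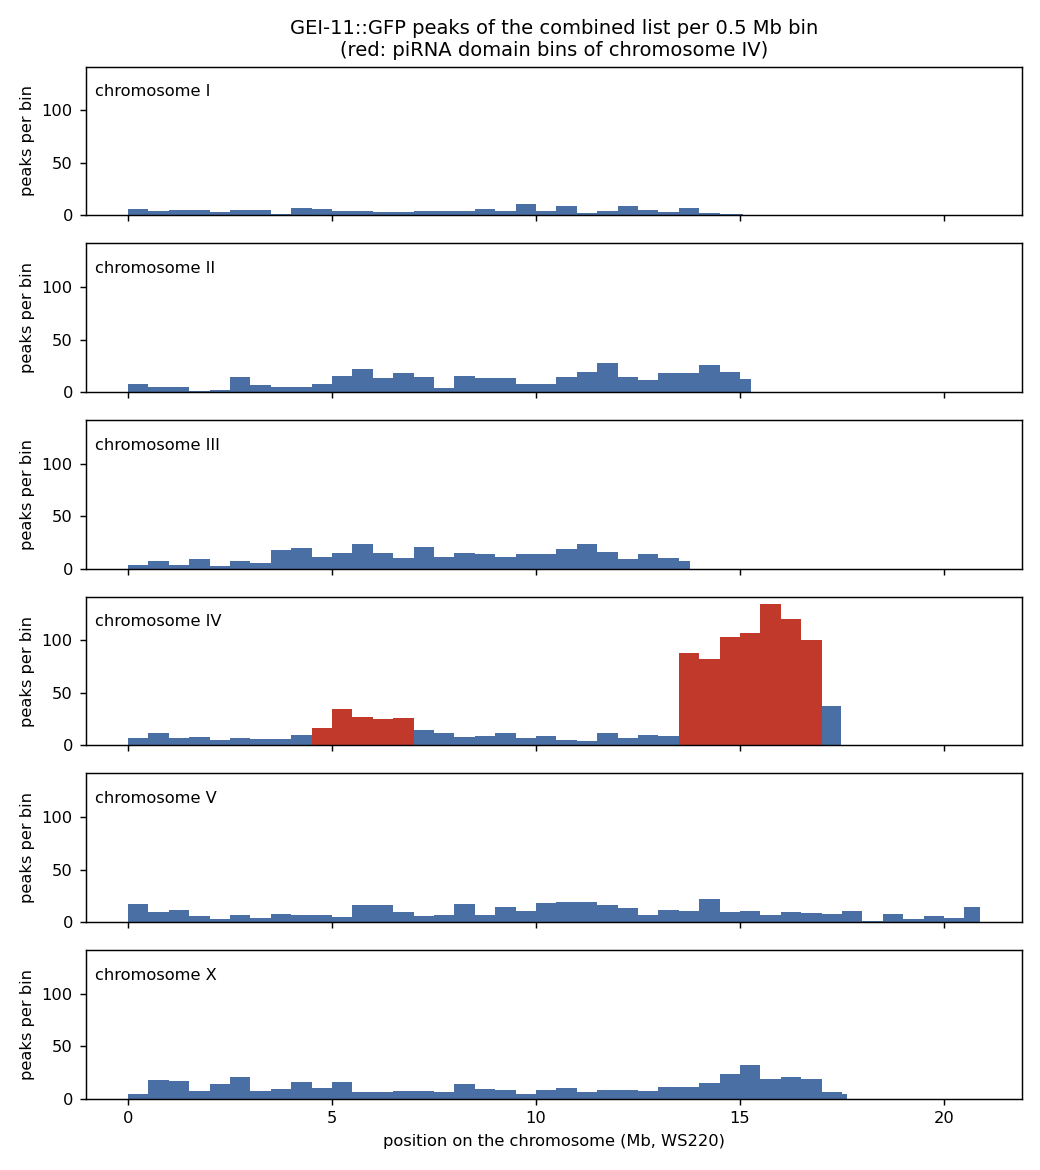
Number of combined peaks (y) in each 0.5 Mb bin along the 6 chromosomes (x, Mb, WS220), 1 panel per chromosome with a shared y axis; bins of the piRNA domains are red. Bins of the right domain hold 82 to 135 peaks, against 1 to 32 in full bins of the other chromosomes.

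The peaks of chromosome IV were concentrated in its piRNA domains. In C. elegans, piRNAs (21U-RNAs) are small germline RNAs that act with the Argonaute protein PRG-1, and most of their genes lie in 2 broad domains of this chromosome. The domain bins held 865 of the 1090 combined peaks on the chromosome, or 79.4%, and 30.8% of the whole list. Peak density was 144 per Mb inside and 19.6 per Mb in the rest of the chromosome, a ratio of 7.34 (95% CI 6.33 to 8.54). Shifted lists placed 35% of the chromosome's peaks there on average and 80.6% at most (circular-shift permutation p = 0.012, adjusted p = 0.019). A small shift can leave the dense stretches within the bins, so this p does not measure how much denser the domains were. The ratio was 8.32 (5.48 to 13.0) in replicate 1, with 122 peaks inside, and 7.96 (6.72 to 9.46) in replicate 2, with 708 inside. The 2 replicate lists are not independent: 293 of the 301 replicate 1 peaks overlapped replicate 2 peaks, and 245 did so at matched length. Fisher's exact p-values between them therefore describe the lists only, and similar shares at matched length follow largely from this overlap. The share of all peaks that fell in the domains was 40.5% in replicate 1 and 33.1% in replicate 2 (Fisher's exact p = 0.011, adjusted p = 0.026). With the 301 strongest peaks of replicate 2 it was 42.9% (Fisher's exact p = 0.62, adjusted p = 1).

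The right domain was the denser. It held 735 combined peaks, 210.0 per Mb, and was 10.7 times (95% CI 9.20 to 12.5) as dense as the chromosome outside the domains (circular-shift permutation p = 0.013, adjusted p = 0.019). Against 67.4% observed, shifted lists placed up to 68.4% of the chromosome's peaks in the right domain. Its 7 bins held 82 to 135 peaks with a median of 103, and the 13 bins between the domains held 4 to 15 with a median of 9. The left domain held 130 peaks, 52.0 per Mb, 2.65 times (2.12 to 3.30) the density outside, and 4.26 times (2.40 to 7.53) in replicate 1. Its 5 bins held 17 to 35 with a median of 26. The fixed test of the left domain was not passed. It takes the share of all 1090 peaks of the chromosome, which the 735 peaks of the right domain hold down, so it does not measure the density of the left domain by itself. The share was 11.9% against 14.9% on average in shifted lists (circular-shift permutation p = 0.32, adjusted p = 0.32), and with peaks placed singly at random p was 0.99 (one-sided, 1000 simulated placements). On the stretch left of the right domain alone, a setting chosen after seeing the data, the left domain held 41.0% of 317 peaks. Shifted lists held 18.6% there on average and 42.0% at most (circular-shift permutation p = 0.024). The density ratio on that stretch was 3.06. The ratio was 4.58 in replicate 1 and 3.73 in replicate 2 under the same setting. The 163 full bins of the other chromosomes held 10.3 ± 6.16 peaks (SD over bins). The fullest of them, between 15 and 15.5 Mb of the X, held 32.

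Domain peaks of the combined list were slightly stronger and, in the right domain, narrower than other peaks. The permutations shuffled single peaks of the whole list. Neighbouring peaks are not independent, so the permutation p-values below describe the lists only. The median −log10 q was 3.72 inside the domains, 0.623 above the median elsewhere (permutation p = 1e-05, adjusted p = 1e-05), and 3.37 inside against 3.05 elsewhere in replicate 2 (permutation p = 0.00053, adjusted p = 0.00079). In replicate 1 the medians were 4.83 and 4.68 (permutation p = 0.90, adjusted p = 0.90), a difference that did not pass the test. By domain, the combined median was 4.56 in the left and 3.65 in the right (permutation p = 1e-05 against elsewhere for each, adjusted p = 1e-05), and that of replicate 2 was 3.73 and 3.32 (permutation p = 0.00053 and 0.0015, adjusted p = 0.00079 and 0.0015). In replicate 1 the left domain lay below the rest, at 3.48, and the right above, at 5.32, and neither passed the test (permutation p = 0.44 and 0.50, adjusted p = 0.75 for each). The domains held 35 of the first 100 combined peaks (95% CI 25.7 to 45.2%), 46.0% of ranks 101 to 300 and 26.9% of ranks 1001 to 2811. Peaks of the right domain were narrow, with a median of 157 bp against 312 bp elsewhere (permutation p = 1e-05, adjusted p = 1.5e-05). The medians were 286 and 369 bp in replicate 1 and 164 and 314 bp in replicate 2 (permutation p = 1e-05 for each, adjusted p = 3e-05 and 1.5e-05). Peaks of the left domain had a median of 322 bp, which did not differ from the rest by the test (permutation p = 0.41, adjusted p = 0.41). In replicate 1 they were narrower, at 309.5 bp against 369 bp (permutation p = 0.018, adjusted p = 0.018), and in replicate 2 the medians were 312 and 314 bp (permutation p = 0.91, adjusted p = 0.91). The strongest right domain peaks spanned 14326775 to 14327448, 13600587 to 13602389 and 14525236 to 14526098, with combined −log10 q of 146, 128 and 112. Those of the left domain spanned 6117574 to 6118201 and 4880378 to 4881142, with 73.7 and 71.4. All 5 were in both replicate lists.

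**Figure D3:**
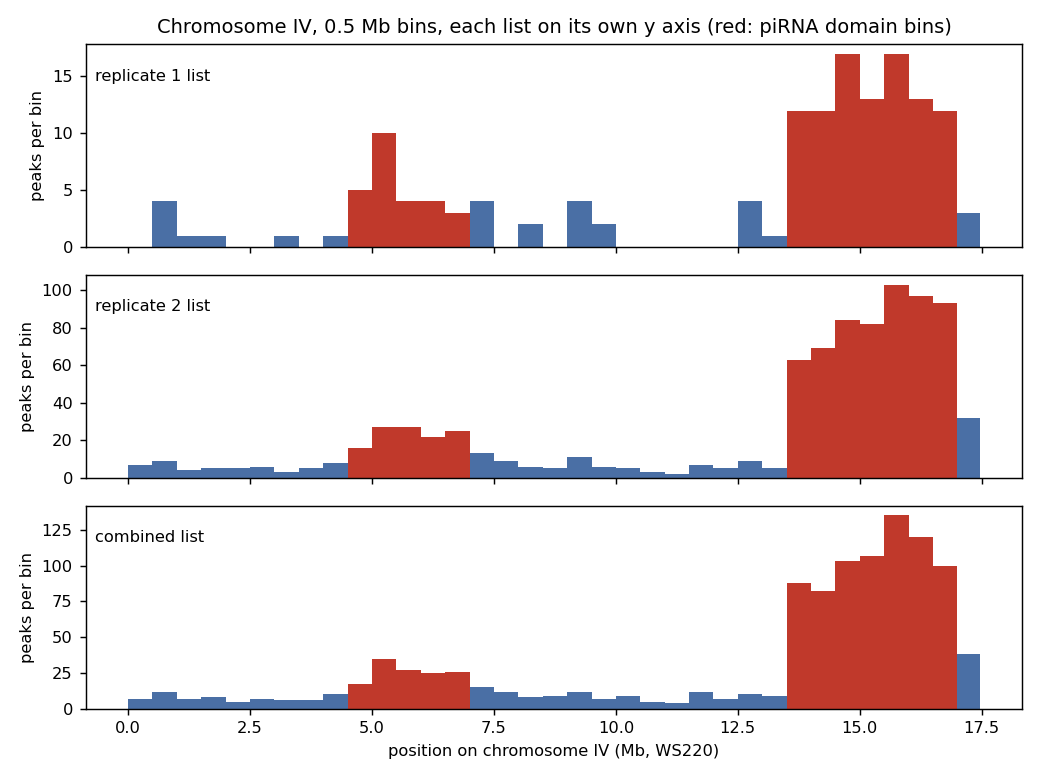
Number of peaks (y) per 0.5 Mb bin of chromosome IV (x, Mb, WS220) in the list of replicate 1, the list of replicate 2 and the combined list, each with its own y axis starting at 0; bins of the piRNA domains are red. The domain bins hold 122, 708 and 865 peaks in turn.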

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

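The settings that leave out the domain bins, confine the left domain to its own stretch, drop narrow peaks or match the list lengths were chosen after seeing the data. No paired analysis was possible because the ChIP and input samples that share numbers had no values for the input. Chromosome ratios for II, III and the X turned from below to above 1 with the domain bins left out (1.21, 1.23 and 1.15) and that for IV from above to below (0.949), while that for V lost its call (0.993). These shares sum to 100%, so removing the domains raises the other ratios by construction, and the low count on chromosome I raises them too. Chromosome II also lost its call with peaks within 1 kb merged (0.939), with replicate 2 at the length of replicate 1 (0.915) and in the list of replicate 1 alone (0.848 to 0.849 over the single lists), and the X with merging (0.909). The cause of these losses was not tested. The left domain gained a call on the stretch left of the right domain (3.06). The difference in median −log10 q between domain peaks and the rest was 0.155 to 0.324 over the single replicate lists and was not called in replicate 1, the shorter list. The median width difference was −81 to −124 bp over those lists, against −129 bp in the combined list. The X ratio was 0.358 to 0.788 over the single lists and 0.358 with replicate 2 at the length of replicate 1, and the left domain ratio 3.16 to 4.26 and 5.82. Under all other settings run, overlaps, the ratios for chromosomes I and IV, the density of both domains together and of the right domain, and the width difference kept their direction and their side of the threshold. The 50% overlap rule left the matched pairs of the correlation unchanged, so it is no check of it. Tests by gene, RNA class and motif, and another value column for the correlation, were not run. The unknown read depth limits any statement on regions missing from replicate 1.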

Other observations

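Outside the piRNA domains, peaks were spread unevenly along some chromosomes, a comparison chosen after the data had been seen. With each chromosome divided into 3 equal parts, the middle part of the X held 91 of 418 combined peaks, 21.8% (95% CI 17.9 to 26.0; exact binomial p = 2.4e-07, adjusted p = 1.2e-06 over 5 chromosomes), with 144 in the left part and 183 in the right. On chromosome V the middle part held 41.3% of 429 peaks (exact binomial p = 0.00059, adjusted p = 0.0015) and on III 39.0% of 351 (exact binomial p = 0.027, adjusted p = 0.045). Chromosome II had 185 of 382 peaks in its right part and 65 in its left, with 34.6% in the middle (exact binomial p = 0.63, adjusted p = 0.78). The test covers the share of the middle part only, so the difference between right and left was not tested. Neighbouring peaks are not independent, so these p-values cover counting error only and are too small where peaks cluster. The call on III, close to the threshold, may not hold beyond counting error, and that on V is uncertain. Chromosome I had 47 peaks in the left, the middle and the right part alike. Chromosome IV was also searched in 10 kb steps, on each side of 10 Mb, for the single stretch that best parted a denser from a sparser density. In the combined list these stretches ran from 13.65 to 17.22 Mb and from 4.65 to 6.92 Mb. They ran from 13.60 to 16.82 Mb and 4.75 to 6.80 Mb in replicate 1, and from 13.65 to 17.29 Mb and 4.65 to 7.59 Mb in replicate 2. The bin after the fixed right domain still held 38 combined peaks.

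The comparisons of spacing and of narrow peaks were also chosen after the data had been seen. Within the right domain the median distance between neighbouring peaks was 2.52 kb, below the 3.30 kb (95% of draws 3.05 to 3.55) of 735 peaks placed uniformly at random in 1000 simulations. In the left domain it was 11.2 kb against 13.2 kb (10.7 to 15.8), within the range of the draws. Uniform placement ignores the uneven density of the right domain, whose bins held 82 to 135 peaks. Such unevenness, or a broad region split into peaks, would also shorten the median distance, so the comparison does not show local clustering beyond them. Of the 146 combined peaks narrower than 50 bp, 141 lay in the right domain, 2 in the left and 3 elsewhere. With these 146 left out the domains were still 6.13 times as dense as the rest of the chromosome. The spacing was not compared without them.

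In the 3 paragraphs that follow, the tests of a single replicate as the source were chosen after the result had been seen, and the others before. The shares of chromosome I by rank tier were also chosen after the data had been seen. The first pattern is the density of the piRNA domains. With peaks within 1 kb merged the ratio was 6.06 (95% CI 5.18 to 7.10), but only 196 of the 863 gaps between neighbouring domain peaks are that short, a limit weighed only after the result had been seen. By the bound set beforehand, a ratio above 2, the split of a broad enriched region would have been excluded; with that limit it stays open. Peaks near the q threshold would leave the stronger 50% of the list below 2, and it was 9.70 (7.82 to 12.1). The lower of the ratios in the single replicate lists was 7.96. A local bias in mappability or in the input reads was not tested here and may remain. The caller scores ChIP reads against input, but the samples include no ChIP from worms without the tagged protein. Peaks were not set against piRNA genes or their motif either, so binding of GEI-11 at piRNA loci stays an untested hypothesis.

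The second pattern is the shorter list of replicate 1. Lists of unrelated positions would overlap no more than the 5.98% of shifted lists, and the overlap was 97.3%. This test was set before the result was seen, but as one of unrelated or mislabelled material, and was narrowed to unrelated positions afterwards. Material of another factor that shares sites was not tested. A lower yield that kept the strongest of the same sites predicts that shared replicate 2 peaks outrank unshared ones. The shared peaks did so with a probability of 0.967. Any other cause that left only the strongest of the same sites in the short list would give a similar value. The value therefore does not single out lower depth or weaker enrichment in replicate 1. These cannot be separated without read counts. The strongest replicate 1 peak, at the right end of chromosome I, is the exception, with a −log10 q of 276 and no overlap in the other lists. The other lists did mark this chromosome end, with a nearby combined peak of −log10 q 6.97 that replicate 2 also held.

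The third pattern is the shortage on chromosome I. It was present in both replicate lists, with ratios of at most 0.353 (upper bound 0.564), so 1 replicate alone is argued against. PeakSeq scales input to ChIP for each chromosome, so a high scale on chromosome I, which carries the ribosomal DNA repeats, may have raised the bar there and removed weak peaks more than strong ones. The odds of a peak being on chromosome I and not on II, III, V or X were 0.685 times (95% CI 0.477 to 0.983) as high in the weaker as in the stronger 50% of the list, in the predicted direction but close to 1 at the upper bound (Fisher's exact p = 0.034, and adjusted p = 0.086 with the other 4 chromosomes). Chromosome I held 21.4% (11.6 to 34.4) of the first 100 peaks outside chromosome IV, near its 18.2% of the extent. It held 4.55% of ranks 101 to 300, 10.4% of ranks 301 to 1000 and 7.07% of the rest. Past the first 100 the share thus did not fall steadily with rank. The ratio to the expected count was 0.364 in the stronger 50% of the combined list, against 0.333 in the whole list. In the 301 strongest replicate 2 peaks it was 0.375. The shortage was therefore not confined to weak peaks, and a loss of weak peaks does not account for all of it. A true lack of weaker sites would look like a raised bar, has the same limit and stays open.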
